A study of Mus musculus with 6 samples.

How the data were processed

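Gene expression was measured in the gastric antrum, the lower part of the stomach, of mice at postnatal day 14. Per the labels, each of 3 littermate pairs held 1 animal homozygous for the Kit K641E allele and 1 wild-type animal. Total RNA was amplified as aminoallyl antisense RNA, coupled to Cy5 or Cy3 and hybridised to mouse oligonucleotide arrays with probes of 70 bases, per the labels' protocols. Each pair was hybridised on 2 arrays with the dyes exchanged, so the series has 6 arrays and 3 replicates, the pair being the replicate.

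The authors deposited 1 value table with 38467 probes and no missing value on any of the 6 arrays. Its values were read as log2 ratios of the 2 channels of an array, as deposited. The scale is an inference from the values: they are signed and their largest size is 5.831, above the 4.8165 that a log10 ratio could reach on a scanner with a maximum of 65535. Base 2 was assumed, and a natural logarithm could not be excluded, so every fold below rests on base 2. The medians of the arrays lay between -0.003 and 0.004, so the arrays had been centred by the authors. The scanner, the background correction and the method of normalization are not given in the sources used here.

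The direction of the deposited ratios is not given in the sources used here either. Across probes, the 2 arrays of pairs 1, 2 and 3 correlated at -0.61, -0.74 and -0.83, so the values follow the dyes. The sign of each array with the mutant in Cy3 was turned, taking red over green as the order. By a rule fixed before the data were examined, the direction is called likely mutant over wild type, because the mutant is in channel 1 of every sample and because Spry4 and Tpbg, which the title of the study's paper names as up-regulated, came out above 0. Since the values follow the dyes, the channel number does not bear on the direction. The direction rests on the assumed order and on Spry4 and Tpbg, which are therefore not independent evidence of it.

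Probes were named from the platform annotation, which gives 1 gene symbol for 22941 probes (59.6%), several for 0 and none for 15526. All 22941 gene identifiers were found in the mouse RefSeq table of assembly GRCm38.p6, which changed 0 symbols; the table was used for names only. Probes of the same gene were averaged, and 5117 genes had several probes. Unnamed probes were tested under their own identifiers, giving 30649 features, of which 15123 are named genes. The annotation marks no control spots, so all probes were kept.

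The 2 turned arrays of a pair were averaged, which cancels a dye effect, and the 3 pair means were tested against 0 with limma's lmFit and eBayes (R 4.3.3, limma 3.58.1), two-sided, with Benjamini-Hochberg adjustment at 0.05. The moderated variance had 2 residual and 1.80 prior degrees of freedom, and the median standard error of a feature was 0.055. Errors given as SE are limma's moderated standard errors over 3 pairs. Array intensities and background were not used here, and the small number of arrays, from 3 pairs, limits the precision.

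Of 23 gene lists fixed before the data were examined, 22 were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 22. They cover the interstitial cells of Cajal, receptor tyrosine kinase feedback and ETS targets, STAT targets, markers of other cell types and tissues the piece could hold, cell cycle, immediate early genes, glycolysis and hypoxia, neighbours of Kit, and sex-linked genes. The remaining list, Kit with Spry4 and Tpbg, is given as values. The genes named are the 12 highest and 12 lowest past the threshold with 1 sign on all 6 arrays, or all that pass if fewer, up to 4 members of each list with the lowest p, and always Kit, Spry4, Tpbg and the sex-linked genes. The rule named 91 genes; 22 further features, among them Etv1, Edn3, Ano1 and Alb, were chosen after their values were seen.

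On simulated data with 200 changed features among 30649, the gene test called 50% of those changed by a log2 ratio of 0.5, 92% at 1 and 100% at 2 and at 3 (50 features each), with 13 false calls. The simulated noise was drawn independently for each feature from limma's fitted spread, and each change had the same size in all 3 pairs. These shares do not apply to changes that differ between pairs, so a feature not called is not shown to be unchanged. Prkcq, for example, had a log2 ratio of 2.42 with an SD of 0.87 over pairs and was not called. Retnla had an SD of 0.12 and was called. With 1 of 22 lists shifted by 0.7 in such noise, camera with the preset correlation called 1 list, the shifted one. With an estimated correlation it called 0. Independent noise suits the preset by construction, so this does not show that the preset holds in the real data. There the estimated correlation of the called lists ran from -0.08 (adipose) to 0.63 (pancreas), with 0.41 for the interstitial cell list.

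The alternatives tried were centring each array on its median, scaling arrays to a common spread, fitting the 6 arrays with the pair as a random block or as independent values, either dye orientation alone, leaving out each pair, testing each probe, a robust prior, other thresholds, camera with an estimated correlation, and the rotation test fry. Chosen after seeing the data were the restriction to probes whose identifiers start with mM, ratios taken relative to the smooth muscle list, a size rule (a log2 ratio of at least 1 on all 6 arrays) and 6 added gene lists, which are given as medians per pair without a test. Figures were drawn with matplotlib 3.10.9.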

Results

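The series compares the antrum of mice homozygous for Kit K641E, an activating mutation of the receptor tyrosine kinase Kit, with that of wild-type littermates at postnatal day 14. Kit is the receptor on which the interstitial cells of Cajal, the pacemaker cells of the gut wall, depend, and these cells are the ones from which gastrointestinal stromal tumours are thought to arise. The question is which transcripts of the antrum differ when Kit carries the mutation. The data are 6 arrays, 2 for each of 3 littermate pairs, each with 38467 probes. Values are log2 ratios, likely mutant over wild type, given as the mean over pairs with limma's SE (n = 3), and folds assume base 2.

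Retnla and S100a8 rose in the mutant antrum. Retnla, a secreted resistin-like protein made by alternatively activated macrophages and by epithelia, had a log2 ratio of 2.80 ± 0.06 (SE, n = 3), a 6.98-fold difference. S100a8, a subunit of the calcium-binding protein calprotectin of neutrophils, had 1.71 ± 0.04, a 3.28-fold difference. Each was higher on 6 of 6 arrays, and the pair means ran from 2.68 to 2.92 for Retnla and from 1.69 to 1.74 for S100a8. Within every pair the 2 arrays differed by more than the pair means did, so the SE over 3 pairs may understate the error. Retnla had 3.324 and 2.525 on the arrays of pair 2, and S100a8 1.555 and 1.824 on those of pair 3. No gene fell at the threshold.

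In the limma test over 30649 features, 2 were higher and 0 lower at an adjusted p of 0.05, both with an adjusted p of 0.041. At an unadjusted 0.05, 840 were higher and 662 lower, against 1532.4 expected by chance. At an unadjusted 0.001, 31 features passed, against 30.6 expected. With arrays scaled to a common spread both had an adjusted p of 0.05012, and with each probe tested on its own 0.06416. Over the 9 alternatives that keep all 3 pairs and a spread for each gene, the adjusted p of each ran from 0.0001695 to 0.2192. The lowest came from taking the 6 arrays as independent, which counts the 2 arrays of a pair as replicates. Among those of the 9 that average the 2 arrays of a pair, it ran from 0.03976 to 0.06416. With any 1 pair left out the fit called 0 of all features, while Retnla stayed between 2.74 and 2.86 and S100a8 between 1.70 and 1.73. Fitting the 6 arrays with the pair as a random block gave 10 higher and 5 lower.

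Kit itself and the genes named in the title of the study's paper were above 0 on average but differed between pairs. Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, had 1.38 ± 0.36, with 0.46 in pair 1, 2.17 in pair 2 and 1.51 in pair 3. Tpbg, which encodes trophoblast glycoprotein, a cell-surface protein, had 1.96 ± 0.42, with 0.82, 2.54 and 2.53. Its 2 probes gave 1.31 and 2.62. Kit had 0.89 ± 0.40, with -0.02 in pair 1, 1.89 in pair 2 and 0.81 in pair 3. None of these passed over all features (limma adjusted p 0.923 for each), and 2 of the 3, Tpbg and Spry4, passed when adjusted over the list alone. That list was taken from the study itself and is not independent evidence.

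**Figure D1:**
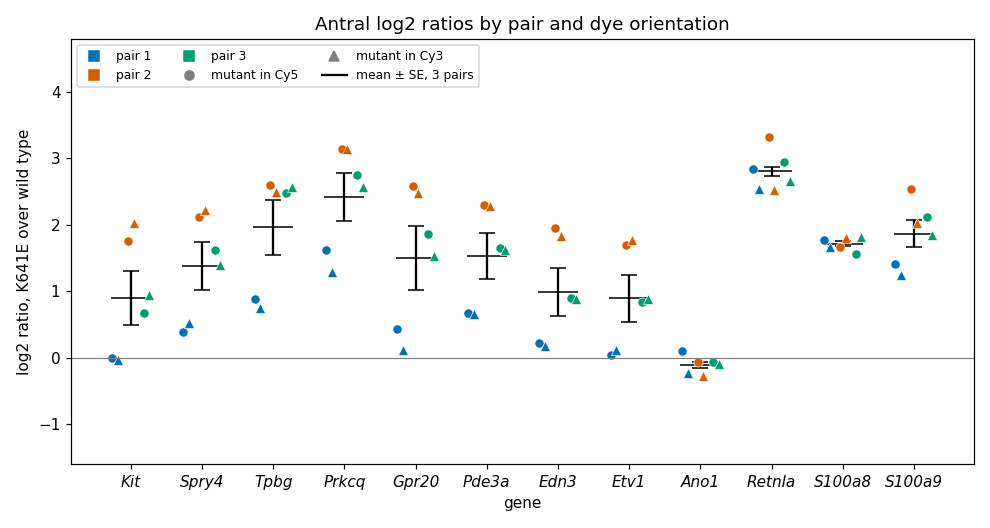
Log2 ratios of 12 genes (y axis, K641E over wild type, log scale of base 2) on each of the 6 arrays, coloured by pair and shaped by the dye of the mutant, with the mean and SE over 3 pairs in black. Kit lies near 0 in pair 1 (-0.02) and at 1.89 in pair 2, while S100a8 lies between 1.56 and 1.82 on all 6 arrays.

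The list of interstitial cell of Cajal genes rose at the preset correlation (camera adjusted p 0.000665), a call that was lost with an estimated correlation (adjusted p = 0.801). Its 14 measured members had a median log2 ratio of 0.68 (0.40 without pair 2, 0.26 with each probe on its own), and 10 of them were above 0. Prkcq, protein kinase C theta, which these cells and stromal tumours express, had 2.42 ± 0.37, and was above 1 on each of the 6 arrays. Pde3a, a cyclic nucleotide phosphodiesterase, had 1.53 ± 0.34, and its 3 probes gave 1.74, 2.35 and 0.51. Gpr20, an orphan receptor, had 1.50 ± 0.48 and Thbs4, thrombospondin 4, 0.62 ± 0.16. Among members chosen after their values were seen, Edn3 had 0.99 ± 0.36 and the transcription factor Etv1 0.89 ± 0.35, while Ano1, the calcium-activated chloride channel of these cells, had -0.11 ± 0.04.

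The call was also lost with fry (adjusted p = 0.809). Of the 22 lists, 0 passed either camera with an estimated correlation or fry, so every list call below rests on the preset correlation. Camera with an estimated correlation also called 0 lists in the simulation with 1 list shifted by 0.7. A call lost with it therefore does not show that a list is unchanged. Adjusted over the list alone, 1 member passed, Prkcq, and 0 passed over all features. The list medians in pairs 1, 2 and 3 were 0.11, 1.21 and 0.56.

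Genes of receptor tyrosine kinase feedback and ETS targets also rose as a list at the preset correlation. Their median was below that of the interstitial cell list over all pairs but not in pair 1 (0.13 against 0.11). The difference between the lists was not tested. The median over 13 members was 0.21, 10 were above 0, and the pair medians were 0.13, 0.24 and 0.43 (adjusted p 0.00508 at the preset correlation, 0.801 with an estimated correlation). Beside Spry4, Spry2 had 0.47 ± 0.13, Spry1 0.35 ± 0.10 and the ETS factor Etv4 0.41 ± 0.11. The 2 probes of Spry1 gave -0.01 and 0.70. No member passed over all features or when adjusted over the list alone. Spry4 was also used to set the direction of the ratios, so the sign of this list is not fully independent of that rule. The list's median was 0.38 without pair 1 and 0.07 without pair 3, where its adjusted p was 0.148. The 8 STAT targets, another branch downstream of Kit, had a median of 0.01 and were not called (adjusted p 0.431). Their member with the lowest p, Cish, had -0.20 ± 0.04.

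The smooth muscle list fell at the preset correlation (adjusted p 0.00333, or 0.801 with an estimated correlation), with pair medians of -0.73, 0.30 and -0.44. Of its 15 measured members, 13 were below 0, with a median of -0.40. Smtn, which encodes smoothelin, had -0.64 ± 0.35, Des, the intermediate filament desmin, -0.40 ± 0.22, and Lmod1, an actin nucleator of smooth muscle, -0.40 ± 0.06. Adjusted over the list alone, Lmod1 was lower, and 0 members passed over all features. Pair 2 had the other sign from pairs 1 and 3, and without pair 1 the list's median was -0.08 and its adjusted p 0.617. The median was -0.43 without pair 2, -0.19 with each probe on its own and -0.23 with the mutant in Cy5 only.

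The fibroblast and endothelium lists fell at the preset correlation (adjusted p 0.0440 and 0.0280, or 0.801 for each with an estimated correlation). Of 12 fibroblast genes, 9 were below 0, with a median of -0.05 and a mean of -0.14. The pair medians were -0.30, 0.03 and -0.15, and the median was -0.01 without pair 1 and -0.19 without pair 2. Decorin, Dcn, had -0.50 ± 0.07 and was lower when adjusted over the list alone, while Col1a2 had -0.50 ± 0.30. Of 9 endothelial genes, 7 were below 0, with a median of -0.14, among them Tie1 with -0.19 ± 0.04 and Esam with -0.38 ± 0.10. The endothelial pair medians were -0.54, 0.07 and -0.03. The fibroblast call ended without pair 1 (adjusted p 0.461), without pair 3 (0.0736) and with the mutant in Cy5 only (0.131). The endothelium call ended with the mutant in Cy5 only (0.0726) and without pair 1 (0.935), where the direction of the test also turned.

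Transcripts of the exocrine pancreas fell as a list, and this rested on pair 1. The 8 members had a median of -2.34 in pair 1, -0.05 in pair 2 and 0.05 in pair 3 (adjusted p 0.0280 over all pairs, 0.801 with an estimated correlation, 0.922 without pair 1, 0.0557 with the mutant in Cy5 only). In pair 1 the elastase gene Cela2a had -2.61 and the carboxyl ester lipase gene Cel -2.27. The liver list, which was added after seeing the data, had medians of -0.06, 3.14 and 1.96 in the 3 pairs over 33 members, and of -0.05, 1.63 and 0.69 over the 15 members whose values had not been looked at when the list was made. Albumin, Alb, had -0.27, 5.58 and 5.14. The interstitial cell list median was also lowest in pair 1.

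The adipose list rose at the preset correlation (adjusted p 0.0353, or 0.801 with an estimated correlation), with a mean of 0.39 and a median of 0.03 over 7 members. Its pair medians were -0.16, 0.42 and 0.24, and its median ran from 0.07 to 0.14 when a pair was left out. Fabp4, the fatty acid binding protein of fat cells and macrophages, had 1.19 ± 0.11, and Cidec, a lipid droplet protein, 0.37 ± 0.06. Both were higher when adjusted over the list alone and 0 members passed over all features. Pck1, an enzyme of gluconeogenesis, had 1.43 ± 0.76, with -0.61, 2.89 and 2.01 in the 3 pairs, beside liver list medians of -0.06, 3.14 and 1.96. Adipoq had -0.31 ± 0.58, and Lep, Plin1 and Lpl lay between -0.01 and 0.03. Leaving out pair 2 or pair 3 ended the list's call (adjusted p 0.252 and 0.856), as did taking the arrays with the mutant in Cy5 only (0.0726).

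**Figure D2:**
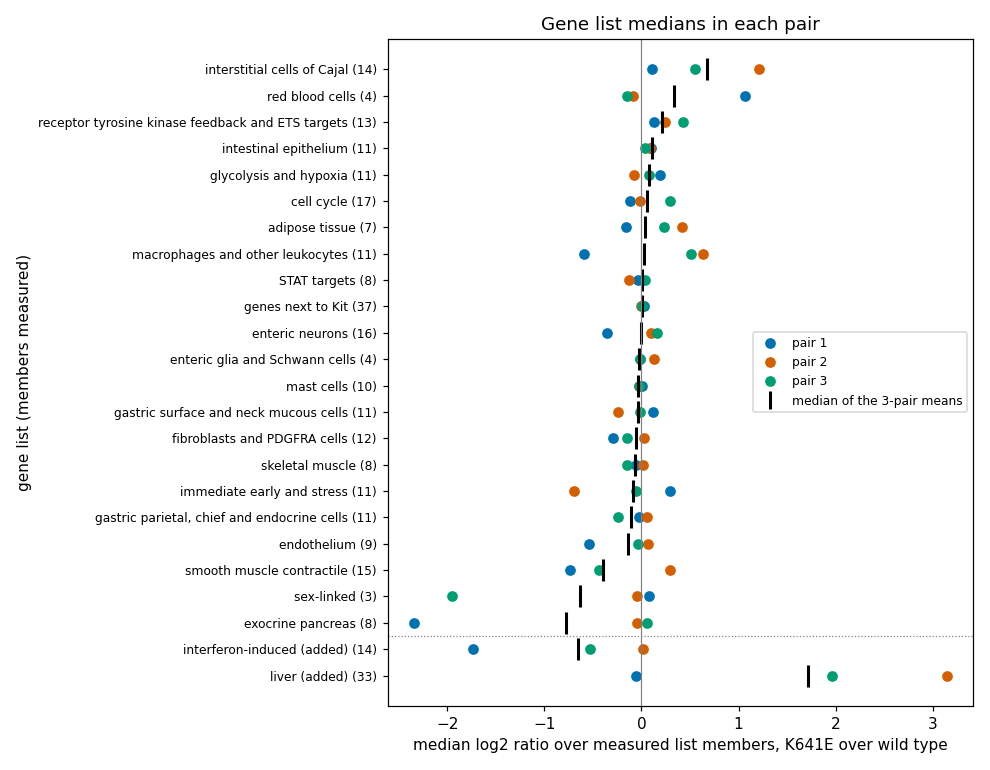
Median log2 ratio (x axis, K641E over wild type) of each gene list (y axis, number of measured members in brackets) in each pair (coloured points), with the median of the members' means over 3 pairs as a black bar; lists under the dotted line were added after seeing the data. The interstitial cell list is above 0 in all 3 pairs (0.11, 1.21 and 0.56), while the pancreas list is at -2.34 in pair 1 only and the liver list, which includes members picked for their high ratios, at 3.14 and 1.96 in pairs 2 and 3 (1.63 and 0.69 over the members not looked at before).

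Lists of other cell types were not called over all 3 pairs. Medians were 0.00 for 16 enteric neuron genes, -0.02 for 4 glial genes, -0.03 for 10 mast cell genes, 0.03 for 11 leukocyte genes and 0.33 for 4 red blood cell genes. Among neuronal genes the neuropeptide gene Vip had 0.56 ± 0.16 and Calb2 -0.25 ± 0.09. Among mast cell genes Hdc, the enzyme that makes histamine, had -0.51 ± 0.15 and the protease gene Mcpt2 0.21 ± 0.05. The leukocyte list had -0.59 in pair 1, 0.64 in pair 2 and 0.52 in pair 3, and it was called higher when pair 1 was left out (adjusted p 3.232e-09). The neuron list was also called higher without pair 1 (0.000956). Lyz2 had 0.62 ± 0.44, and its 4 probes gave between 0.03 and 1.08. The red blood cell list had 1.06 in pair 1, and -0.09 and -0.15 in the others.

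Epithelial lists were close to 0. The 11 surface and neck mucous cell genes had a median of -0.04, with -0.24 ± 0.12 for Tff1, and were called lower without pair 1 (adjusted p 0.00735) and with the mutant in Cy3 only (0.0265). The 11 parietal, chief and endocrine cell genes had a median of -0.10, with 0.66 ± 0.22 for the pepsinogen gene Pga5. The 11 intestinal genes had a median of 0.11. Among them Fabp1, the fatty acid binding protein of liver and intestine, had 1.59 ± 0.31 and Reg3g, an antimicrobial lectin, 0.88 ± 0.30. The 8 skeletal muscle genes had a median of -0.07.

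Cell cycle genes (17 members) had a median of 0.06, immediate early genes (11) -0.09, and glycolysis and hypoxia genes (11) 0.08, and none of these lists was called. Without pair 1, immediate early genes were called lower (adjusted p 0.000414) and cell cycle genes higher (0.0124), and without pair 2 glycolysis and hypoxia genes higher (0.0208). Immediate early genes differed between pairs, with 0.30, -0.69 and -0.06. The test had the other sign from the median for the STAT targets, glia and neighbours of Kit, and the median and mean had opposite signs for the parietal, chief and endocrine cell list. Sex-linked genes differed within pair 3: Eif2s3y, a gene of the Y chromosome, had -5.06 there against -0.03 and -0.05 in pairs 1 and 2, and Kdm5d had -1.95 against 0.22 and -0.15. The sex-linked list was not called (adjusted p 0.182), and Xist and Ddx3y are not named among the probes.

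The 37 measured neighbours of Kit had a median of 0.01 and were not called as a list (adjusted p 0.807). Srd5a3, a steroid reductase family gene, had -0.53 ± 0.05 and was lower when adjusted over the list alone; its 2 probes gave -0.88 and -0.18. Hopx, a homeodomain-only protein, had 2.01 ± 0.47, with 0.78, 2.94 and 2.33 in the 3 pairs, and did not pass. A test for donor-strain sequence kept around Kit, on the share of neighbours called, was set beforehand but not run. With 0 neighbours called over all features and 2 of 30649 features called, it could not decide, so that source stays open.

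By the size rule chosen after seeing the data, 8 features had a log2 ratio of at least 1 on all 6 arrays and 0 had -1 or less. Besides Prkcq, Retnla and S100a8 they were S100a9, the other subunit of calprotectin, with 1.87 ± 0.21, Fibin with 2.06 ± 0.29, Enpep, the glutamyl aminopeptidase, with 1.83 ± 0.25, and the unnamed probes mMC024575 with 2.17 ± 0.21 and mTG035793 with 4.36 ± 0.21. The 2 probes of Enpep gave 0.50 and 3.15. Without pair 1 the count was 97, without pair 2 it was 23, and without pair 3 it was 9. Liver genes such as Alb are among the 97, and how many was not counted. Of the 33 liver genes measured in the added list, 21 had a pair mean of at least 1 in both pairs 2 and 3.

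Across features, the pair means of pairs 2 and 3 correlated at r = 0.45. Those of pairs 1 and 2 correlated at -0.08 and those of pairs 1 and 3 at 0.11. In the same order the rank correlations were 0.20, -0.14 and 0.03. The features include the liver genes, whose list medians were 3.14 and 1.96 in pairs 2 and 3. Features are not independent replicates.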

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

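The tests on sex within pairs, on a mutant piece without the mutant allele and on a genotype effect on liver and pancreas transcripts were chosen only after the result was seen, as were the added liver and pancreas lists. Of the 33 liver and 20 pancreas genes measured in these added lists, 0 and 0 are in a list fixed before the data were examined; which of them the antrum itself expresses cannot be read from ratios. Over the 6 arrays, 135 results were examined for 1 array far from the others, and 9 had one. Chance flags about 1 in 20 groups of independent samples, but the 2 arrays of a pair hold the same RNA, so that share is not the chance value here. In pair 2 with the mutant in Cy5, Akp3 lay at 0.854, Entpd2 at 0.508, Myocd at -0.184 and the glia list median at 0.230. In pair 2 with the mutant in Cy3, Gast lay at -0.323 and Krt19 at -0.604. In pair 1, Car9 lay at -0.298 with the mutant in Cy5, and Cish at -0.001 and Gata2 at 0.014 with the mutant in Cy3.

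The first pattern weighed is the calls of Retnla and S100a8. A dye effect is argued against, since the smaller orientation mean was 0.896 times the larger at the median over both genes. The test of sex set beforehand, Y-linked genes within 0.5 in the mean over pairs, was not met (Eif2s3y -1.71, Kdm5d -0.63). Sex as the source in every pair is argued against by the 2 pairs whose Y-linked genes stayed within 0.5. The median log2 ratio of both genes was 2.21 there, against 2.25 in pair 3. Genes are called for like values over pairs, so the likeness of these 2 medians is not separate evidence. Exchanging mutant and wild type within pairs gives only 4 assignments, too few for a share under 0.05; 1 of the 4, the real one, gave 2 calls and the highest other gave 0. A genotype effect on both genes is a hypothesis.

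The second pattern is the shift of the interstitial cell list. More muscle wall in the mutant pieces is argued against as its whole source, since the smooth muscle median was -0.587 times the interstitial cell median and the enteric neuron median 0.000307 times. More mast cells are argued against by a mast cell median of -0.0474 times the interstitial cell median, with a member SD of 0.365 on the same scale. A mutant piece in pair 1 that lacks the allele stays open: the lowest ratio of Tpbg and the probe mTG035793 on the arrays of pair 1 was 0.752, but the probe was picked for being high on all arrays, its target is not given in the sources used here, and Tpbg was named by the study from these samples. A genotype effect, on the number of these cells or on their transcripts, is the biological explanation the design gives, and it may differ in size between pairs.

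The third pattern is liver transcripts in pairs 2 and 3 and pancreas transcripts in pair 1. A genotype effect present in every pair is argued against, since each list had a pair with a median no larger than 0.0765 in size, as did the pancreas list fixed before the data were examined (-0.05 and 0.05 in pairs 2 and 3); an effect in some pairs only is not excluded. Liver tissue in the mutant pieces may be a source, but the test set for it was not met: 20% of the 15 liver genes not looked at before (3) reached 1 in both pairs, under the 50% set as the bound against it, and Ttr, abundant in liver, had 0.63 and -0.12. Likewise 41.7% of 12 such pancreas genes (5 genes) reached -1 in pair 1. Both tests are void, because every member looked at before had a mean farther from 0 than every member left for the test, so the choice of genes set the share; of these 15 liver genes, 15 were above 0 in pair 2 and 14 in pair 3, so tissue carried over with the pieces stays open.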

How the results depend on the processing

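Chosen after seeing the data were the restriction to probes starting with mM, ratios relative to the smooth muscle list, and the size rule. The count of higher genes, 2, became 0 with scaled arrays, 0 with the mutant in Cy5 only, 1 in Cy3 only, 0 with each probe on its own and 0 whichever pair was left out, where no feature passed; it became 10 with the pair as a random block and 25 with 6 independent arrays, where lower genes numbered 5 and 14. Relative to the smooth muscle list, 163 were higher and 3 lower, but there limma's prior gave every feature the same spread and all features shifted by a median of 0.28, so its calls follow the mean ratio and do not measure agreement over pairs. The 2 genes remained called with centring, the robust prior, both other thresholds and mM probes. Lists called higher, 3, and lower, 4, became 0 and 0 with an estimated correlation and 0 and 0 with fry; 1 list was lower with the mutant in Cy5 only, 5 were higher relative to the smooth muscle list, and leaving out a pair gave 1 to 6 higher and 2 to 4 lower. The endothelium list's test turned without pair 1 (adjusted p 0.935), while its median ran from -0.242 to -0.0583 when a pair was left out. The size rule's 8 features became 26 relative to the smooth muscle list and 9 to 97 when a pair was left out, and its 0 lower features 3 to 4. The interstitial cell list stayed above 0 in all 13 alternatives (0.26 with each probe on its own to 0.96 relative to smooth muscle) and past the threshold in 11 of them. All 11 kept the preset correlation, and the call was lost with an estimated correlation (camera adjusted p 0.801) and with fry (0.809). The 11 include the 6 arrays taken as independent and the ratios relative to smooth muscle, which do not measure agreement over pairs. Of the 113 named genes only Retnla and S100a8 were called, and they stayed past the threshold in 7 and 6 of 13 alternatives. All lost calls of single genes are therefore theirs. Over all single genes, 1377 values kept direction and side of the threshold, 13 lost a call, 34 gained one and 44 changed sign without a call on either side. By the direction of the test, the numbers for lists were 232, 25, 10 and 18; by the median, 37 of 286 list values had another sign than the main one, among called lists pancreas without pair 1 (0.0249), and endothelium (0.138) and fibroblasts (0.226) relative to smooth muscle. Except where the construction shows it, the cause was not tested. The requirement of a value on at least 1 array per pair removed nothing and was not run, and camera takes no block, so lists have no value there. With each probe on its own, a single gene is given by its probe with the lowest p. The counts there are over all probes, and the list values over every probe of the members. Signal over background was not used here, so its limits are not known.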

Other observations

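The interferon, squamous, neutrophil, macrophage and second pancreas lists, the size of each list relative to smooth muscle, and the single genes of the first 2 paragraphs were chosen after seeing the data, and these added lists were not tested. Interferon-induced genes (14 members) had medians of -1.74, 0.02 and -0.53 in pairs 1, 2 and 3. Irf7, the interferon regulatory factor, had -0.98 ± 0.19 (SE, n = 3) and Oasl2 -1.50 ± 0.40, both below 0 on 6 of 6 arrays. Of the leukocyte list, Cd74 had -2.42, 0.70 and 0.61, and H2-Aa -2.24, 1.01 and 0.85. Squamous epithelial genes (12 members), which in the mouse mark the forestomach, had medians of 0.27, -0.11 and 1.45, with Lor at 4.48 and Krt13 at 3.78 in pair 3.

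The neutrophil list had a median of 0.18 over 14 members and of 0.15 over the 12 members other than S100a8 and S100a9, and Mpo, a granule enzyme, had 0.02 ± 0.04. Lcn2 (0.59 ± 0.24), Mmp9 (0.34 ± 0.11) and Chil1 (0.20 ± 0.07) were above 0 on 6 of 6 arrays and did not pass over all features. The list of alternatively activated macrophage genes had a median of 0.12 over 10 members, Retnla included. Arg1, which is in it and is also abundant in liver, had 0.52, 2.83 and 1.83 in the 3 pairs, beside liver list medians of -0.06, 3.14 and 1.96. Mrc1 had 0.28 ± 0.05, while Chil3 had 3.33, -2.36 and -1.76 in the 3 pairs. The second pancreas list (20 members) had medians of -1.45, -0.08 and -0.11, and of -0.61, 0.08 and -0.21 over the 12 members not looked at when it was made.

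The interstitial cell list median minus the smooth muscle list median was 0.84, 0.91 and 1.00 in pairs 1, 2 and 3 (SD 0.079, n = 3), against an SD of 0.55 for the interstitial cell list alone. The receptor tyrosine kinase feedback list went the other way, with 0.86, -0.05 and 0.87 relative to smooth muscle (SD 0.53) and an SD of 0.15 alone. Relative to the smooth muscle list, Kit had 0.71, 1.60 and 1.25 (SD 0.45). A hypothesis is that the share of muscle wall in the pieces may account for part of the difference between pairs in the interstitial cell list. It was not tested apart from the value that started it, and a smooth muscle median of -0.587 times the interstitial cell median argues only against muscle as the whole source.

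The unnamed probe mTG035793 had the mean ratio farthest from 0 of all 30649 features, 4.36 ± 0.21. The other 36 probes of its identifier series had means between -0.15 and 0.12.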
